A study of Mus musculus with 2 samples.

How the data were processed

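Whole lung of SP-C I73T mice was lavaged, perfused and digested with collagenase, red cells were lysed, and single-cell libraries were made with 10x 3′ v3 chemistry. There were 2 libraries, 1 titled injured and 1 titled control, and groups were taken from the titles because the treatment tags ran against them. The deposited values were whole-number UMI counts per gene and cell barcode, written by Cell Ranger 4.0.0 per the file headers and not normalized before deposit. The submitters' processing notes list STAR 2.7.2c, featureCounts 1.6.3 and DESeq2 1.26.0 and 1.28.1 with builds GRCm38 and mm10; the role of these tools for the present libraries was not stated, and the extraction text also describes bulk RNA. The matrices held 32285 genes, of which 32158 were found in GENCODE M21, and 38 symbols stood on more than 1 gene ID and were kept apart by ID, which took Ddit3 out of the ER stress response list.

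Barcodes needed at least 500 UMIs, at least 200 genes and a mitochondrial share of at most 15%. No deposited barcode had fewer than 500 UMIs, so the UMI minimum removed none. Of 2702 barcodes in the injured library 153 were under the gene minimum and 310 over the mitochondrial limit, which removed 356. Of 2674 in the control library the numbers were 110, 261 and 332. Doublets were scored per library as the share of simulated doublets among 40 neighbours, and the top-scoring cells, 0.8% per 1000 cells, were removed (44 and 44, 1.88% of the 4688 cells that passed). This left 4600 cells of 5376 barcodes, with medians of 1425.5 and 1672.5 genes and mitochondrial shares of 5.32% and 4.74%.

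Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes found in at least 3 cells gave 30 principal components, from which a shared-neighbour graph with 20 neighbours was built (Jaccard index of at least 1/15) and clustered with the Leiden method at resolution 1 and seed 1, without batch integration. The 27 clusters were named from 27 marker lists. The type with most markers among the 10 leading genes of a cluster also needed the most markers, and at least 3, that were 3-fold above the other cells and found in 20% of the cluster, and otherwise the cluster was called mixed or left unnamed. After the clusters were seen, an AT1 and AT2 mixed cluster and the AT2-like cluster were merged as alveolar epithelial-like, and T cell and ILC2 clusters were merged. The planned AT2 lists were run on the merged class, because the AT2-like cluster held 19 injured cells. Shares carry exact binomial 95% intervals.

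Counts were summed per library and class for classes with at least 50 cells in both libraries, and given as CPM with exact Poisson intervals and ratios with exact conditional intervals. Log2 ratios had 10 CPM added to both sides. A count of 0 was bounded at 3 counts, and members at 0 were also placed at that bound. The 18 gene lists used members with at least 10 counts over both libraries, lists with at least 5 such members, 1000 Poisson draws for the interval, and 10000 random lists of the same size matched in 20 bins of mean expression. Shares of cells with a UMI were taken after thinning to 1000 UMIs, which left out 276 and 340 cells with fewer. The computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, python-igraph 0.11.9 and leidenalg 0.10.2.

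With 1 library per group no test across samples, p-value or standard error was computed. The groups, filters, markers, lists, size rule and naming rule were chosen before the data were examined. Genes were named by the size of the log2 ratio: the 12 highest and 12 lowest in the whole library and the 6 highest and 6 lowest per class among genes with at least 50 counts. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor, sex-linked and unnamed genes were left out, as was a gene under 20% of its highest level in any class of the library where it was higher. Also named were Sftpc, class markers and up to 4 members of each printed list, in class lists only those that met the same 20%, apart from members given as examples of those that did not. This choice for lists, and the medians without members under 20%, were made after the results were seen, and as the level was taken in the library where a member was higher, the choice depends in part on the change. Krt19, Postn, Ccl3, Ccl5, Il33 and Il4 in the whole library, Mki67 and Pdcd1lg2 in alveolar macrophage-like cells, Hbegf and Itgb6 in alveolar epithelial-like cells, H2-K1 in endothelial-like cells and Pdcd1 in T cell or ILC2-like cells were chosen after their values were seen, as were the interferon and MHC class I lists in further classes.

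The procedure was tested on simulated data. For genes drawn from 13148 at whole-library depth, true log2 ratios of 2 and -2 came back with medians of 1.98 and -1.99, and as 1.49 and -1.08 with the pseudocount, and 96% and 78% passed the size rule on that scale; in a class with 5% of the UMIs the shares were 100% and 100%. For ratios of 1 and -1 these shares were 70% and 42%, and 88% and 76%. The calls reported used CPM ratios without the pseudocount, so these shares do not carry over to them. Some classes were also shallower than the simulated one, with 149041 UMIs in control alveolar epithelial-like cells. Of simulated unchanged lists 3.5% and 4.5% fell outside the middle 95% of random lists. These lists were random genes with independent counting noise, so such shares follow from the setup. They do not show how often lists of co-expressed genes, in libraries of unlike composition, would fall outside. Of 117 doublets added to each library, 37.6% and 47.0% of the same number of top scores were added ones, so many doublets are expected to remain. Alternatives tried covered the barcode filters, doublet removal, clustering resolution, clustering of each library alone, scaling, the pseudocount, the count minimum, equal weight per cell, thinning and the marker minimum, and some added later. Lists in interstitial macrophage-like, monocyte-like, fibroblast-like and NK cell-like cells were left out because 1 library held fewer than 50 such cells.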

Results

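Single-cell 3′ libraries were prepared from collagenase-digested whole lung of C57BL/6 mice that carry the I73T mutation of surfactant protein C, the alveolar type 2 (AT2) cell protein encoded by Sftpc. In this line a single oral dose of tamoxifen (175 mg/kg) removes a neomycin cassette and raises expression of the mutant protein. The study compared lung at steady state with lung 14 days after injury, and its title asks about a role of inflammatory eosinophils. There was 1 library titled injured and 1 library titled control. The treatment tags ran against the titles, since the library titled injured was tagged untreated and the library titled control was tagged tamoxifen treated. Groups here follow the titles, no measured value decided between the labels, and each direction given is between the libraries as titled. How many animals went into each library was not stated.

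The library titled injured held 2702 barcodes with 22314603 UMIs, and the library titled control held 2674 barcodes with 17207816 UMIs. After filtering, 2302 and 2298 cells remained, with 19928088 and 15996150 UMIs and medians of 3277.5 and 4481 UMIs per cell. Neither group had a replicate, so no test across samples was possible, and all 95% intervals cover counting error only. A gene was called higher or lower by size alone, at 1.5-fold or more between the scaled levels in CPM (counts scaled to the library or class total). UMIs of Scgb1a1, a secretoglobin of airway secretory cells, were found in 82.8% of B cell-like cells of the injured library and in 99.7% of those of the control library, at median depths of 3381.5 and 4483.5 UMIs. Free RNA of this gene was thus present in both libraries. Xist was counted in both libraries, at 699 and 952 CPM, and the Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 counts in both.

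Sftpc, which carries the mutation (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081 on the minus strand of GRCm38), was higher in the injured library as a whole. It stood at 369.6 CPM (95% interval 361–378) there and at 139 CPM (133–144) in the control library, a ratio of 2.67 (2.54–2.80). In the AT2-like cluster, cluster 20, the level was 28738 CPM (27255–30280.2) over 19 injured cells and 22438 CPM (21456–23454) over 63 control cells. The ratio of 1.28 (1.20–1.37) stayed under the 1.5-fold rule, but its log2 value of 0.36 rose to 0.59 with size factors and to 1.22 as a median over thinned cells, both past that rule. In cluster 18, which held markers of both alveolar type 1 (AT1) and AT2 cells, Sftpc stood at 4315 CPM over 82 injured cells and at 114 CPM (45.7–234) over 20 control cells, the latter from 7 counts. The alveolar epithelial-like class drew most injured cells from cluster 18 and most control cells from cluster 20, and its Sftpc level was 5218 CPM against 13204 CPM, 2.53-fold (2.41–2.66) higher in the control library. The class held 1322942 UMIs in the injured and 149041 in the control library, so its depth also acts on the whole-library ratio. As a median over thinned cells the log2 ratio was 0 in the whole library and -10.40 in this class. The median injured cell of the class held no Sftpc UMI, so the 10 CPM added to both sides sets the size of the latter value. These 3′ counts do not separate mutant from wild-type transcripts.

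The composition of the cells differed between the libraries in both myeloid and lymphoid classes. Neutrophil-like cells made up 25.4% (23.6–27.2; 584 of 2302) of the injured library and 5.48% (4.59–6.49; 126 of 2298) of the control library. Macrophage-like cells with complement C1q transcripts, named interstitial macrophage-like, made up 11.4% (10.2–12.8) against 0.0435% (0.00110–0.242), which was 263 cells against 1. In the injured library the alveolar macrophage marker Chil3 stood at 16877 CPM in these cells and at 20898.5 CPM in alveolar macrophage-like cells. The class name thus does not settle whether they were resident interstitial macrophages. Conventional type 2 dendritic cell (cDC2)-like cells made up 5.69% (4.78–6.72) against 1.57% (1.10–2.16), and mature dendritic cell-like cells 4.26% (3.47–5.16) against 0.392% (0.179–0.742). Classes with a smaller share in the injured library included B cell-like cells (2.52%, 1.92–3.25, against 13.9%, 12.5–15.4), classical monocyte-like cells (0.738%, 0.431–1.18, against 4.57%, 3.75–5.504) and nonclassical monocyte-like cells (0.391%, 0.179–0.741, against 4.18%, 3.40–5.08). Natural killer (NK) cell-like cells made up 0.825% (0.498–1.29) against 3.92% (3.16–4.79), and blood endothelial-like cells 3.95% (3.19–4.83) against 17.0% (15.5–18.6).

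Alveolar macrophage-like cells made up 14.2% (12.8–15.7) of the injured and 17.5% (16.0–19.1) of the control library. T cell or type 2 innate lymphoid cell (ILC2)-like cells made up 9.34% (8.18–10.6) against 13.1% (11.7–14.5), secretory-like cells 3.48% (2.77–4.31) against 5.13% (4.27–6.12), and fibroblast-like cells 1.74% (1.24–2.36) against 3.44% (2.73–4.27). Mesothelial-like cells stood at 0.999% (0.634–1.495) against 0.348% (0.150–0.685). The intervals overlapped for alveolar epithelial-like cells (4.39% against 3.61%), ciliated-like cells (0.738% against 0.609%) and plasmacytoid dendritic cell-like cells (0.478% against 0.348%). Unnamed clusters held 9.47% (8.30–10.7) against 4.87% (4.03–5.84) of the cells. Of the cells in named immune classes, neutrophil-like cells were 33.7% (31.5–36.0) in the injured and 8.44% (7.08–9.97) in the control library. Several clusters came almost wholly from 1 library and may mark that library rather than a cell type, namely cluster 7 of interstitial macrophage-like cells (263 and 1), cluster 0 of neutrophil-like cells (425 and 10), clusters 3, 4 and 19 of alveolar macrophage-like cells (326 and 0, 0 and 304, 1 and 98) and clusters 14 and 25 of endothelial-like cells (0 and 112, 26 and 1). The alveolar macrophage difference changed sign under 5 of the other settings, and with each library clustered alone the endothelial difference shrank from -13.1 to -1.14 percentage points and the interstitial macrophage difference from 11.4 to 3.65 points. The cDC2-like difference of 4.12 points fell to 0.665 with no minimum UMIs or genes, 0.864 at resolution 0.5 and 0.388 at resolution 2, and that of alveolar epithelial-like cells, 0.776, was -1.27 with each library clustered alone. The secretory-like difference of -1.66 was -5.57 in that setting, the T cell or ILC2-like difference of -3.72 was -5.71 with a mitochondrial share of at most 10%, and the fibroblast-like difference of -1.70 was -2.69 with at most 25%. Lavage before digestion, collagenase and red cell lysis can all act on such shares, and their effect was not tested.

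**Figure D1:**
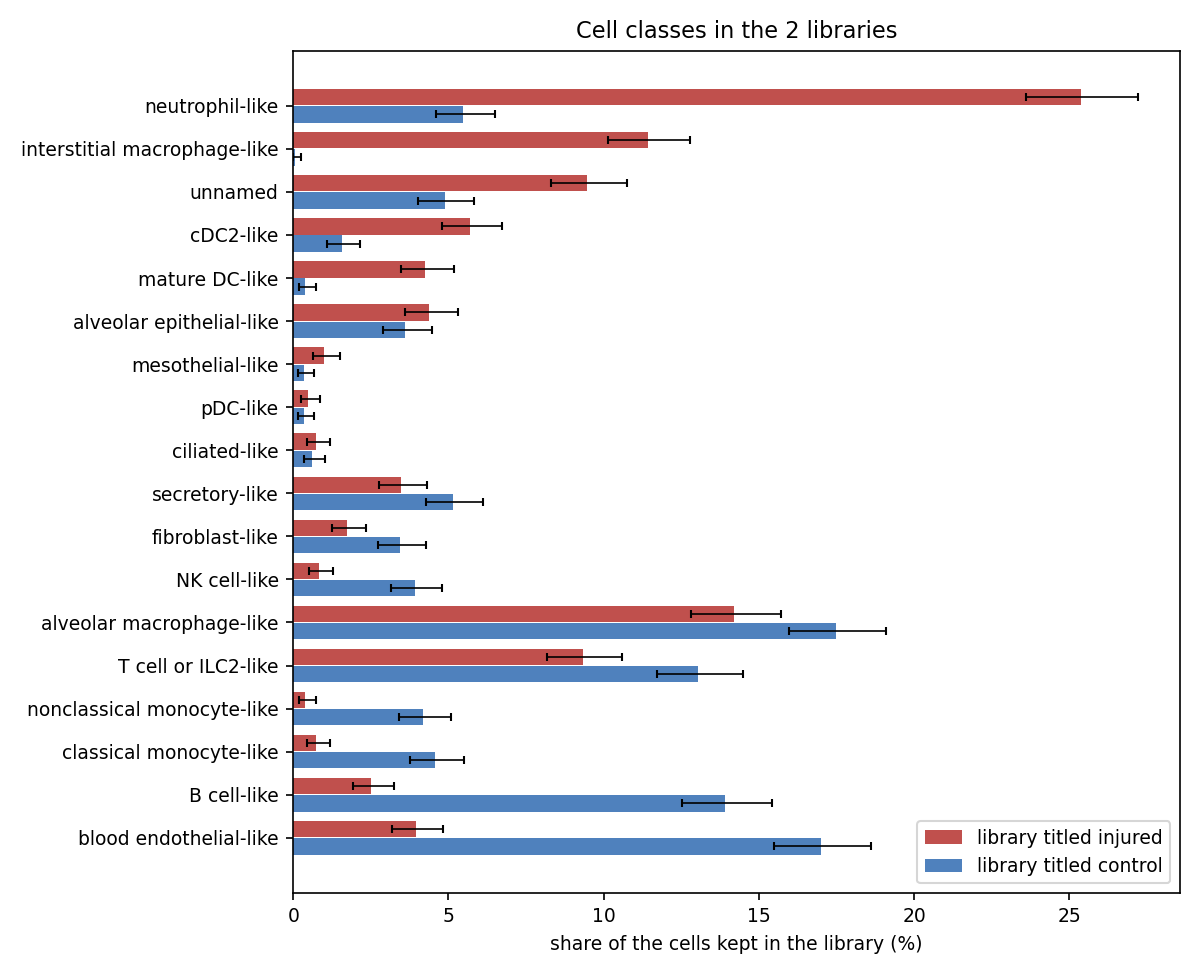
Share of the cells kept (%, horizontal axis) in each named class for the library titled injured (2302 cells) and the library titled control (2298 cells), with exact 95% binomial intervals that cover counting error only. Neutrophil-like cells stand at 25.4% and 5.48%, and blood endothelial-like cells at 3.95% and 17.0%.

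Eosinophils, the cells named in the study's title, formed no cluster. UMIs of at least 2 of the 5 markers Ccr3, Il5ra, Prg2, Epx and Ear6 were found in 4 of 2302 injured cells (0.174%, 0.0474–0.444) and in 0 of 2298 control cells, and all 4 cells fell in the neutrophil-like cluster 0. With each cell thinned to 1000 UMIs, 0 of 2026 injured cells and 0 of 1958 control cells passed, but thinning leaves out cells with fewer UMIs, among them 3 of those 4. B cell-like and T cell or ILC2-like cells, the background classes, also gave 0. Epx, which encodes eosinophil peroxidase, had 0 counts in both libraries. No deposited barcode had fewer than 500 UMIs and the lung was lavaged before digestion, so these values do not show that eosinophils were absent from the tissue. Ccr3 had 5 and 4 counts, Prg2 7 and 2, and Il5ra, an interleukin 5 receptor gene, 5 and 23, which was 5.73-fold (2.13–19.3) lower in the injured library. Without thinning, at least 1 of the 5 markers was found in 5 of 58 injured and 12 of 320 control B cell-like cells. The classes that held the Il5ra counts were not computed, so the lower level may follow the smaller share of B cell-like cells rather than eosinophils. Ear6, an eosinophil-associated ribonuclease gene, was higher in the injured library at 21.4 CPM against 2.81 CPM, 7.60-fold (5.58–10.6), with most of its UMIs in alveolar macrophage-like cells. Ear1, of the same gene family, went the other way at 47.3 CPM against 284.6 CPM, 6.01-fold (5.61–6.46) lower.

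Siglecf, a sialic acid-binding lectin of mouse eosinophils and alveolar macrophages, stood at 24.5 CPM (22.4–26.8) in the injured and 51.6 CPM (48.1–55.2) in the control library. At 1000 UMIs per cell it was found in 15.8% (12.8–19.2; 85 of 538) of neutrophil-like cells of the injured library and in 0 of 113 (0%, 0–3.21) of those of the control library. Without thinning these shares were 25% and 3.97%, at median depths of 2053.5 and 2690.5 UMIs. The injured neutrophil-like cells with Siglecf lay mainly in cluster 0 (82 of 382 cells, against 3 of 156 in cluster 6), and control neutrophil-like cells lay mainly in cluster 6. In alveolar macrophage-like cells the order was the other way, with 1.53% (0.4998–3.54) in the injured and 9.94% (7.06–13.5) in the control library, or 38.2% and 63.2% without thinning. The background in T cell or ILC2-like cells was 1 of 215 and 0 of 299 cells, at median depths of 4895 and 5883 UMIs.

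**Figure D2:**
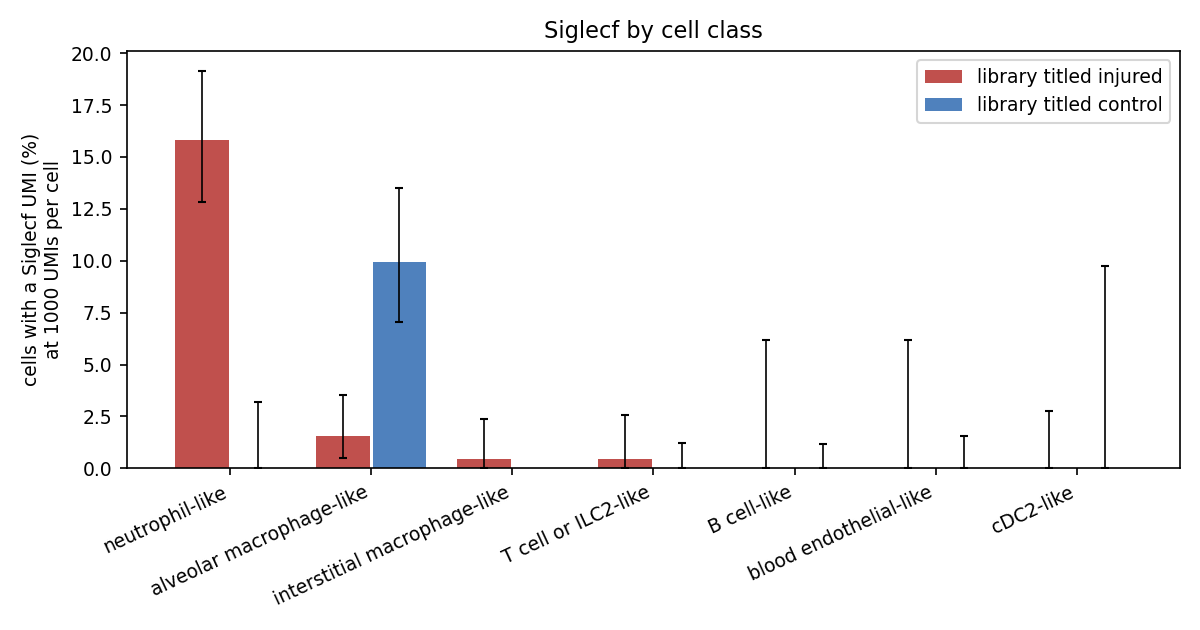
Share of cells with a Siglecf UMI (%, vertical axis) by class after thinning each cell to 1000 UMIs, with exact 95% binomial intervals (counting error only); the control library has no interstitial macrophage-like bar because it held 1 such cell. Neutrophil-like cells of the library titled injured stand at 15.8%, and alveolar macrophage-like cells at 1.53% in the injured and 9.94% in the control library.

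Summed over all cells, the injured library held more transcripts of macrophage activation and matrix remodelling genes. Arg1, the arginase of alternatively activated macrophages, stood at 727 CPM (715–739) against 5.94 CPM (4.80–7.26), 122-fold (100.1–151). Spp1, which encodes osteopontin, stood at 6323 CPM (6288–6358) against 171 CPM (165–178), 36.9-fold (35.6–38.4). The complement genes C1qa, C1qb and C1qc were 62.4-fold (50.8–77.7), 42.4-fold (36.1–50.03) and 69.9-fold (53.3–93.5) higher. Mmp12, macrophage elastase, was 37.8-fold (30.0–48.5) higher, Pf4 30.9-fold (24.8–38.9), Timp1, an inhibitor of metalloproteinases, 41.4-fold (30.7–57.1) and AA467197 39.7-fold (34.2–46.3). Clu, which encodes the chaperone clusterin, was 22.9-fold (20.7–25.3) higher, and Retnla 18.2-fold (17.3–19.2). Ccl24, the chemokine eotaxin-2, stood at 78.8 CPM (75.0–82.8) from 1571 counts against 0.2501 CPM (0.0681–0.640) from 4 counts.

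The classes that supplied these transcripts in the injured library differed. Interstitial macrophage-like cells held 55.7% of the Arg1 counts, 71.6% of C1qa, 71.8% of Mmp12, 82.0% of Pf4 and 61.6% of Ccl24. Alveolar macrophage-like cells held 62.9% of Spp1, secretory-like cells 90.5% of Retnla, alveolar epithelial-like cells 67.9% of Clu, and mesothelial-like cells 46.9% of Timp1. In the injured library Fabp1 was 26.9-fold (22.8–31.8) lower and Cpne5 29.3-fold (22.7–38.4) lower, both held mostly by control alveolar macrophage-like cells. The B cell genes Ly6d, Cd79a, Cd79b and Ebf1 were 13.1-fold (11.8–14.5), 11.5-fold (10.6–12.6), 10.8-fold (9.75–11.9) and 8.74-fold (7.89–9.69) lower. Gzma, a granzyme of NK cells, was 11.1-fold (10.2–12.01) lower, Tmem100 10.9-fold (9.67–12.4), Inmt 35.9-fold (26.9–48.9), Plac8 8.61-fold (8.12–9.14), Ms4a4c 15.9-fold (13.4–19.0) and Ifi27l2a 8.92-fold (8.41–9.47).

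Among the gene lists fixed in advance, summed whole-library counts move with the class shares and the depth per cell of each class as well as with expression. Alveolar epithelial-like cells, whose shares had overlapping intervals, held 1322942 of 19928088 UMIs in the injured and 149041 of 15996150 in the control library. Depth alone can thus raise surfactant and transitional genes in these sums. In the profibrotic macrophage list 11 of 13 members were higher and none lower (median log2 ratio 1.43, 95% interval 1.35 to 1.55, percentile 100 among 10000 matched random lists), with Mmp14 16.6-fold, Cd63 5.03-fold and Apoe 4.72-fold higher. In the alternative macrophage activation list 8 of 12 were higher (0.81, 0.78 to 0.85, percentile 100), and in the extracellular matrix list 12 of 16 (0.98, 0.90 to 1.05, percentile 100), with Fn1 8.15-fold and Col6a1 4.55-fold higher and Postn 6.93-fold lower. The transitional epithelial state list had 11 of 16 higher (1.16, 1.06 to 1.26, percentile 100), with Krt8 10.3-fold higher and Krt19 2.24-fold lower. The surfactant and lamellar body list had 9 of 12 higher (1.06, 0.99 to 1.15, percentile 100), with Sftpd 4.31-fold and Sftpb 3.14-fold higher and Sftpa1 3.11-fold lower. With each cell weighted the same, the medians fell to 0.14 for the surfactant and 0.28 for the matrix list, and a pseudocount of 50 CPM gave 0.59, 0.45, 0.43 and 0.94 for surfactant, matrix, transitional and profibrotic genes.

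Of the type 2 and eosinophil recruitment list, 9 of 15 members were higher and 5 lower (0.82, 0.69 to 0.89, percentile 100). Ccl17 was 11.2-fold, Ccl22 5.95-fold and Il33 3.77-fold higher, whereas Ccl5 was 2.43-fold lower. The counts of the type 2 cytokines were small, at 6 and 23 for Il13, 2 and 11 for Il4 and 5 and 5 for Il5. The type 2 median was 0.49 with each cell weighted the same, and a pseudocount of 50 CPM gave 0.23 for type 2, 0.23 for chemokine and -0.58 for interferon genes. The monocyte and neutrophil chemokine list had 9 of 13 higher (0.61, 0.50 to 0.69, percentile 100), with Cxcl16 9.31-fold and Cxcl2 2.27-fold higher and Ccl3 1.97-fold lower. The interferon response list had 13 of 13 lower (-1.48, -1.59 to -1.36, percentile 0), with Isg15 7.25-fold, Ifit3 20.1-fold and Ifitm3 4.05-fold lower. The major histocompatibility complex (MHC) class I list had 6 of 11 lower and none higher (-0.66, -0.71 to -0.60, percentile 0), with H2-T23 2.54-fold and H2-Q7 2.55-fold lower. The medians lay inside the middle 95% of random lists for ER stress response (0.10, percentile 69.5), inflammatory cytokines (0.18, 90.3), lipid handling (0.28, 91.9), MHC class II (-0.16, 10.6), endothelial activation (0.14, 88.0), cell cycle (0.24, 94.7), T and NK effector (0.01, 38.9), and dissociation and immediate early genes (-0.06, 18.1).

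In the alveolar macrophage-like class all but 1 of the 327 injured cells came from cluster 3, and the 402 control cells came from clusters 4 and 19. Spp1 stood at 11738 CPM (11656–11820) against 363 CPM (348–378), 32.4-fold (31.0–33.8). Msr1, a scavenger receptor, was 24.7-fold (18.6–33.6) higher, Ptgs1 25.4-fold (18.1–36.7), Wfdc17 10.7-fold (9.80–11.7) and AA467197 53.3-fold (38.01–77.2). Lower genes included Fabp1 (30.0-fold, 24.8–36.5), Cpne5 (31.2-fold, 23.4–42.5), Igflr1 (28.8-fold, 18.6–46.8), Acaa1b (13.9-fold, 10.9–18.1), Phlda1 (8.67-fold, 7.22–10.5) and Spag11b, at 3 against 440 counts (163-fold, 55.6–796). Spp1 was among the 10 leading genes of cluster 3, and Fabp1, Cpne5, Acaa1b and Spag11b among those of cluster 4, so these values also describe how the clusters were separated.

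The alternative macrophage activation list had 6 of 11 members higher and 3 lower in alveolar macrophage-like cells (median 0.93, 0.89 to 0.95, percentile 100). Of the members, 6 stood under 20% of their level in another class, as with Arg1 at 410.0 CPM in injured cells here and 3932 CPM in interstitial macrophage-like cells, so free RNA or doublets may account for their ratios. Without these, 2 of 5 were higher and 2 lower (median 0.39), with Chil3, a chitinase-like protein, 1.91-fold higher and Pdcd1lg2 3.90-fold lower. In the profibrotic list 8 of 13 were higher and 1 lower (0.84, 0.70 to 0.99, percentile 100), and without 4 such members 4 of 9 were higher and 1 lower (median 0.48), with Cd63 3.78-fold and Trem2 2.51-fold higher. Cell cycle genes were higher in 8 of 12 cases (0.86, 0.68 to 0.95, percentile 100), with Birc5 22.5-fold and Mki67 3.33-fold higher. Cells of the unnamed cluster 21 (42 injured and 32 control), led by Top2a, Mki67 and Birc5, were in no class, so the cell cycle values of all classes leave them out. MHC class II had 6 of 9 lower (-0.45, -0.56 to -0.38, percentile 0.755), with H2-DMa 1.89-fold lower. The chemokine list had 6 of 12 lower and 4 higher (-0.37, -0.43 to -0.23, percentile 0.15), with Ccl2 3.62-fold and Ccl7 3.77-fold lower. The medians of lipid handling (-0.08, percentile 46.7), inflammatory cytokines (-0.19, 13.8) and interferon response (0.03, 75.2) lay within the range of random lists, with Abcg1 2.31-fold, Pparg 2.34-fold and Tnf 6.21-fold lower. Dissociation and immediate early genes were lower in 8 of 13 cases (-0.62, -0.82 to -0.45, percentile 0.01), with Fosb 4.34-fold lower, and another scaling moved the median of all genes in this class by 0.11. In this class 7 of 9 MHC class II, 8 of 12 chemokine and 12 of 13 dissociation genes stood under 20% of their level in another class, so free RNA stays open for them. A pseudocount of 50 CPM brought the medians of alternative activation, profibrotic, cell cycle, chemokine and dissociation genes to 0.38, 0.48, 0.26, -0.17 and -0.34, and the lipid handling median changed sign with size factors (0.0224).

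Within the alveolar epithelial-like class all 15 measured members of the transitional epithelial state list were higher in the injured library (median 2.23, 1.77 to 2.52, percentile 100). This list holds keratins and injury-associated genes that regenerating AT2 cells turn on. Most injured cells came from cluster 18 (82 injured and 20 control), led by AT1 markers such as Ager and Aqp5. Most control cells came from the AT2-like cluster 20 (19 and 63), so a difference between AT1 and AT2 cells may account for part of these ratios. Cldn4, a claudin, stood at 623 CPM (581–667) against 33.5 CPM (10.9–78.3), Sfn 13.6-fold, Hbegf 18.9-fold and Itgb6 5.46-fold higher, and Fn1 and Plaur stood under 20% of their level in another class. Clu stood at 5850 CPM (5720.2–5982) against 114 CPM (66.4–183), 51.3-fold (32.0–88.1), and Sprr1a, a cornified envelope gene, was at least 18.9-fold higher (502 counts against 0). Adgrg1, Sorcs2 and Foxq1, also at 0 counts in the control class, were at least 11.8-fold, 8.19-fold and 7.25-fold higher. Lower were the lysozyme genes Lyz2 (164-fold, 142–189.8) and Lyz1 (683-fold, 119–27342, 1 count against 77), Cbr2 (76.5-fold, 53.5–113), Cox6a2 (36.8-fold, 20.3–71.4), Bex2 (266-fold, 70.6–2249, 2 counts against 60) and Sftpa1 (25.4-fold, 23.4–27.6). Clu, Cldn4 and Itgb6 were among the 10 leading genes of cluster 18, and Sftpa1 and Bex2 among those of cluster 20, so these values also describe how the clusters were separated.

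MHC class II genes were lower in 6 of 6 cases in this class (-1.15, -1.51 to -0.83, percentile 0.08), but each stood under 20% of its level in cDC2-like cells, so free RNA stays open. MHC class I genes were higher in 6 of 10 cases (1.13, 0.72 to 1.33, percentile 98.9), with Tapbp 4.65-fold and H2-K1 2.37-fold higher. Of these 10, 5 stood under 20% of their level in another class, and with the members at 0 placed at their bound the median was 0.63 and the count 5. Surfactant and lamellar body genes had 5 of 12 higher and 2 lower (0.46, percentile 83.0), with Scd1 4.54-fold higher. The ER stress response list had 8 of 16 higher (0.41, percentile 51.9), with Calr 3.17-fold higher and Asns 3.44-fold lower. With size factors these medians turned to -0.16 for surfactant and -0.0446 for ER stress response genes. Interferon response (0.66, percentile 42.9) and cell cycle (1.01, percentile 87.7) lay within the range of random lists, and at the bounds of their members at 0 their medians were 0.22 and -0.42. Type 2 recruitment and chemokine genes had fewer than 5 measured members. Dissociation and immediate early genes were higher in 12 of 13 cases (1.74, 1.25 to 2.02, percentile 100; 1.45 at the bound of the member at 0), 10 of the 13 at under 20% of their level in another class. Injured cells came mostly from cluster 18 (median depth of the class 8566 UMIs) and control cells from cluster 20 (class median 1218 UMIs), and another scaling moved the median of all genes by -0.63. In cluster 18 alone the transitional median was 1.19 and the MHC class II median turned to 1.79, with 0.59 for MHC class I and 1.01 for dissociation genes.

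**Figure D3:**
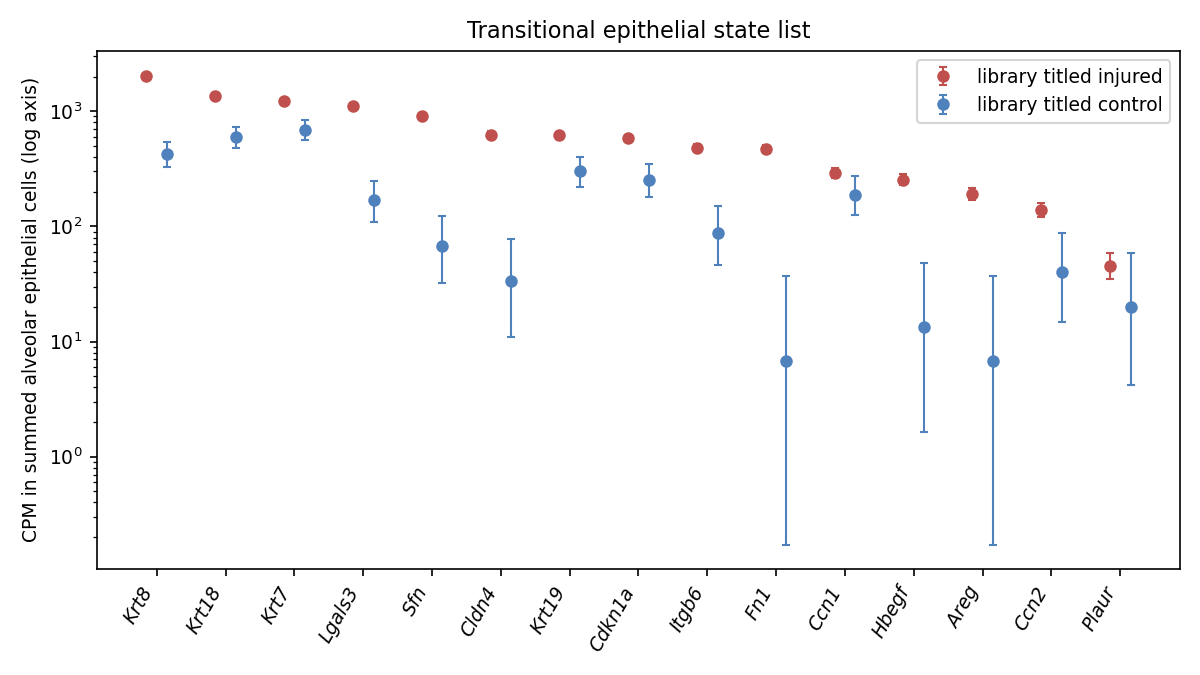
Level of each measured member of the transitional epithelial state list in summed alveolar epithelial-like cells (CPM, logarithmic vertical axis) for the 2 libraries, with exact Poisson 95% intervals that cover counting error only. All 15 members stand higher in the library titled injured, as with Cldn4 at 623 against 33.5 CPM. Most injured cells came from the mixed AT1 and AT2 cluster 18 and most control cells from the AT2-like cluster 20.

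Blood endothelial-like cells of the injured library had higher levels of endothelial activation genes and lower levels of interferon response and MHC class I genes. Of the activation list, 6 of 8 members were higher and 1 lower (median 0.97, 0.78 to 1.27, percentile 99.98). Lrg1, a secreted glycoprotein of activated endothelium, stood at 982 CPM (875–1098) against 43.4 CPM (31.7–58.1), 22.6-fold (16.5–31.6), and Vwf, von Willebrand factor, was 4.19-fold higher. Ankrd37 (41.3-fold, 25.2–72.3), Bnip3 (14.4-fold, 9.28–23.3), Adora2a (13.3-fold, 6.93–27.4) and Sema7a (8.07-fold, 5.72–11.5) were also higher. The interferon response list had 9 of 13 lower and none higher (-1.10, -1.40 to -0.66, percentile 0), 4 of the 13 at under 20% of their level in another class, with Bst2 2.998-fold and Ifit1 2.55-fold lower, and the related GTPase gene Iigp1 was 7.28-fold (4.49–12.6) lower. MHC class I had 7 of 11 lower (-1.00001, -1.11 to -0.78, percentile 0), with H2-Q7 2.38-fold and H2-K1 2.06-fold lower. Fabp4 was 17.1-fold (7.24–53.03) lower and Cyp1a1 at least 17.2-fold lower (0 against 171 counts). Ccl21a and Mmrn1, both lymphatic endothelial genes, were at least 23.7-fold and 7.24-fold lower, with 0 counts in the injured class. No cluster was named lymphatic endothelial, so these values may not describe blood endothelial cells. Dissociation genes were lower in 7 of 12 cases (-0.65, percentile 0.08). Of all 12, 7 stood under 20% of their level in another class, so free RNA stays open for them. Too few cell cycle genes were measured. The class drew on cluster 2 (65 injured and 278 control cells), cluster 14 (0 and 112) and cluster 25 (26 and 1), of which Vwf was a leading gene. The sums thus compare partly different clusters of the libraries, and cluster 2 was not run alone. A pseudocount of 50 CPM gave -0.59 for interferon genes, and equal weight per cell -0.22 for dissociation genes.

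T cell or ILC2-like cells of the injured library had higher levels of 10 of the 14 members of the T and NK effector list and a lower level of 1 (median 0.74, 0.61 to 1.01, percentile 100). Of the members, 6 stood under 20% of their level in NK cell-like cells, so free RNA stays open for them. Il2ra, the interleukin 2 receptor alpha chain, stood at 335 CPM (304–369) against 23.9 CPM (17.3–32.0), 14.1-fold (10.3–19.6). Foxp3, the transcription factor of regulatory T cells, was 14.1-fold (8.87–23.6) higher, Ctla4, an inhibitory receptor gene, 6.73-fold, Tnfrsf4, a costimulatory receptor gene, 7.33-fold and Pdcd1 9.10-fold. Il2ra, Ctla4, Tnfrsf4 and Ctla2a were among the 10 leading genes of cluster 8, where injured cells were more frequent, so these values also describe how the clusters were separated. Tnfrsf9 was 86.7-fold (33.4–321) higher, Calca 66.7-fold (28.2–207) and Ctla2a 9.43-fold (8.27–10.8), and Tff1 at least 33.1-fold (67 counts against 0). The Calca UMIs lay in 9 of 215 injured and 2 of 300 control cells, so few cells set that ratio. Cd40lg was 5.60-fold (2.90–12.1) lower, Rflnb 3.28-fold (2.59–4.19), Hsph1 3.99-fold (2.52–6.58) and Ifi213 3.97-fold (2.36–7.08). Foxp3 UMIs were found in 6.51% (3.61–10.7; 14 of 215) of injured and 0.669% (0.0811–2.40; 2 of 299) of control cells thinned to 1000 UMIs, and in 18.1% and 3% without thinning, while B cell-like cells had 0 of 58 and 0 of 314. Cell cycle genes were higher in 8 of 12 cases (1.02, 0.69 to 1.24, percentile 100) and fell to a median of 0.0724 with doublets kept. Dissociation genes had a median of -0.06 (percentile 3.08). Injured cells came mainly from cluster 8 (148 and 74 cells) and control cells from cluster 5 (67 and 226). Within cluster 8 alone the effector median was 0.21 and within cluster 5 alone 0.37, and another scaling moved the median of all genes in the class by -0.35.

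Neutrophil-like cells of the injured library had lower levels of Rsad2, Ifi27l2a, Isg15, Rtp4, Ifit1 and Ifit3, the 6 genes with the lowest ratios. Rsad2 had 1 count against 225 in the control library (759-fold lower, 135–30106), Ifi27l2a was 86.1-fold (60.5–127) lower, Isg15 54.3-fold (39.1–77.5), Rtp4 47.4-fold (28.1–86.3) and Ifit1 102-fold (38.8–380.5), and Ifit3 was at least 115-fold lower (0 against 102 counts). Higher were Scimp (352 counts against 0, at least 34.8-fold), Id2 (25.5-fold, 14.8–48.0), Cd177, a neutrophil surface glycoprotein (25.4-fold, 10.8–78.6), Creb5 (22.4-fold, 9.52–69.4), Cish (70.3-fold, 12.5–2787, 1 control count) and Prnp (68.8-fold, 12.2–2728, 1 control count). Dissociation genes were higher in 3 and lower in 2 of 13 cases (0.20, percentile 78.4; -0.29 with size factors). Injured cells came from clusters 0 and 6 (425 and 159) and control cells mainly from cluster 6 (116 of 126). Cd177 was among the leading genes of cluster 0, and another scaling moved the median of all genes in the class by -0.49.

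Secretory-like cells all came from cluster 9, and the genes named here are those with the largest ratios. In the injured library Lcn2, lipocalin 2, was 76.5-fold (46.1–137) higher, Retnla 44.6-fold (42.1–47.4), the mucin gene Muc5b 62.9-fold (33.8–132), the acidic chitinase gene Chia1 40.01-fold (26.6–62.9) and Cp, ceruloplasmin, 45.3-fold (24.9–91.7), with Lrg1 at 274 counts against 3 (149-fold, 50.5–728). The glutathione transferase genes Gstm1 and Gsta3 were 5.75-fold (4.41–7.62) and 3.30-fold (2.63–4.18) lower, Aldh3a1 4.59-fold (2.19–11.1), and Krt15 at least 18.2-fold lower (0 against 89 counts). Dissociation genes were higher in 10 of 11 cases (0.97, 0.76 to 1.33, percentile 97.9; 0.60 with a pseudocount of 50 CPM; each under 20% of its level in another class) and cell cycle genes in 6 of 7 (0.75, percentile 86.3), and another scaling moved the median of all genes by -0.14.

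B cell-like cells, all from cluster 1 (58 injured and 320 control cells), had higher levels of Jchain, Xbp1, Fkbp11, Prdx4 and Slpi, among the genes with the largest ratios, in the injured library. Jchain, the joining chain of polymeric antibodies, was 19.2-fold (17.9–20.6) higher and Xbp1, a transcription factor of plasma cells, 6.14-fold (4.67–8.07), with Fkbp11 13.8-fold (7.83–25.4), Prdx4 5.92-fold (3.81–9.21) and Slpi 372-fold (201–780). No cluster was named plasma cell, and these sums do not show how many of the 58 injured cells held the transcripts. Lower were Ifi27l2a (8.29-fold, 5.67–12.6), Ms4a4c (4.68-fold, 2.70–8.88), Ly6d (3.83-fold, 3.30–4.47) and the histone gene Hist1h1e (5.70-fold, 2.17–21.2). Cell cycle genes were lower in 6 of 8 cases (-0.70, -1.18 to -0.51, percentile 0.33), or in 5 with a median of -0.49 when the 3 members at 0 were placed at their bound (-0.30 with a pseudocount of 50 CPM), and dissociation genes had a median of 0.31 (percentile 95.6). No list was computed in interstitial macrophage-like, monocyte-like, fibroblast-like or NK cell-like cells, since each class held fewer than 50 cells in 1 library.

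**Figure D4:**
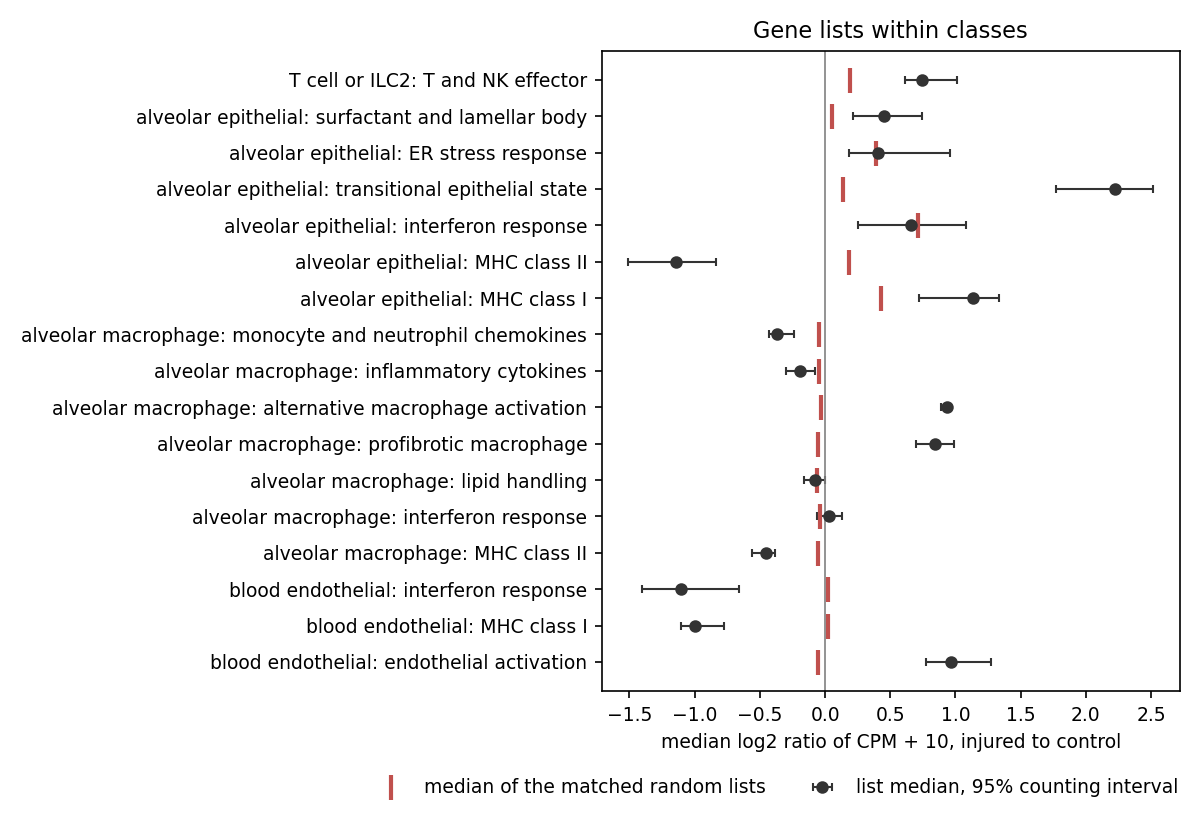
Median log2 ratio of CPM + 10, injured to control (horizontal axis), for gene lists within classes. Points are list medians with 95% counting intervals and bars are the medians of matched random lists, with the transitional epithelial state list at 2.23 in alveolar epithelial-like cells and the interferon response list at -1.10 in blood endothelial-like cells.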

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

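The settings with only cells of at least 2000 UMIs, cluster 18, 8 or 5 alone, a total without genes over 1%, class lists without members under 20% of their highest class level, and doublets kept for named genes, were chosen only after the results were seen, and all other settings before. No paired analysis was possible because each group held 1 library. Of 14 class shares under 124 alternatives, 94 values stayed within the counting interval, 25 moved and 5 called differences changed sign. Among the 25, the alveolar epithelial-like difference of 0.776, whose interval spanned 0, also changed sign. Of 46 list medians under 441 alternatives, 310 stayed, 130 moved and 1 called median changed sign. In all the sign changed under 14 of the 441, otherwise for medians inside the middle 95% of random lists. Of 108 named genes under 216 alternatives, 204 stayed and 12 moved with the same sign. The cause was not tested for the values below, except where a setting itself shows it.

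Shares are given as injured minus control in percentage points. The alveolar macrophage-like difference, -3.29, turned to 0.945 with only cells of at least 2000 UMIs, to 0.877 with no minimum UMIs or genes, to 0.404 with a mitochondrial share of at most 25%, to 0.872 with doublets kept and to 0.933 at resolution 0.5. It was -0.366 with at least 1000 UMIs and 500 genes, -6.03 with a mitochondrial share of at most 10% and -1.02 with each library clustered alone. The interstitial macrophage-like difference was 15.3 with no minimum, 15.1 at resolution 0.5 and 3.65 with each library clustered alone. The cDC2-like difference was 0.665 with no minimum, 0.864 at resolution 0.5, 0.388 at resolution 2, 5.95 with each library alone and 6.25 with only cells of at least 2000 UMIs. The endothelial-like difference was -9.52 with at least 1000 UMIs and 500 genes, -9.39 with a mitochondrial share of at most 10%, -1.14 with each library alone and -6.22 with only cells of at least 2000 UMIs. With that last setting the differences were also 13.3 for neutrophil-like, -4.85 for classical monocyte-like, -14.3 for B cell-like, 3.16 for alveolar epithelial-like and -2.97 for secretory-like cells. B cell-like cells stood at -13.4 with at least 1000 UMIs and 500 genes, T cell or ILC2-like cells at -5.71 with a mitochondrial share of at most 10%, and fibroblast-like cells at -2.69 with at most 25%. Each library clustered alone gave -1.27 for alveolar epithelial-like and -5.57 for secretory-like cells. Resolution 0.5 gave no value for 2 of the 14 classes.

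Cells with at least 1 of 5 eosinophil markers, in place of 2, made up 1.53% of the injured and 0.204% of the control library, as the wider rule takes in more cells, and the other 6 values stayed. Of these 31 injured cells, 21 were alveolar macrophage-like, the class with most Ear6 UMIs, and 3 were neutrophil-like. Of the 4 control cells, 1 was alveolar macrophage-like and 1 neutrophil-like. The log2 ratio of Sftpc was 0.59 in AT2-like and -1.97 in alveolar epithelial-like cells with size factors. As the median over thinned cells it was 1.22 in AT2-like cells, 0 in the whole library, where the median cell held none in both libraries, and -10.40 in alveolar epithelial-like cells. In the latter class the median injured cell held none, so the pseudocount sets the size of that value.

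List medians with size factors were 0.74 for alternative activation and -0.73 for MHC class I in the whole library, 0.57 for T and NK effector genes, and 1.04 for alternative activation and -0.35 for MHC class II in alveolar macrophage-like cells. In alveolar epithelial-like cells they were 1.60 for the transitional state, -1.73 for MHC class II, 0.61 for MHC class I and 1.22 for dissociation.

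A pseudocount of 1 CPM, which shrinks ratios less, gave whole-library medians of 1.48 for surfactant, 1.91 for transitional, 1.68 for type 2, 0.72 for chemokine, 1.12 for alternative activation, 1.998 for profibrotic, -2.01 for interferon and 1.44 for matrix genes. It gave -1.31 for B cell-like cell cycle, 1.53 and 1.34 for T cell or ILC2-like cell cycle and effector, 2.03 for alveolar epithelial-like and 1.37 for secretory-like dissociation genes. In alveolar macrophage-like cells it gave -0.45 for chemokines, 1.31 for profibrotic, -0.61 for MHC class II, 1.51 for cell cycle and -1.28 for dissociation genes. A pseudocount of 50 CPM, which shrinks them more, gave 0.59, 0.43, 0.23, 0.23, 0.65, 0.94, -0.58 and 0.45 for the same whole-library lists in the same order and -0.56 for MHC class I. It gave -0.30 for B cell-like cell cycle, 0.36 and 0.44 for T cell or ILC2-like cell cycle and effector, 0.64 and 1.05 for alveolar epithelial-like MHC class I and dissociation, -0.59 for endothelial-like interferon and 0.60 for secretory-like dissociation genes. In alveolar macrophage-like cells it gave -0.17 for chemokines, 0.38 for alternative activation, 0.48 for profibrotic, 0.26 for cell cycle and -0.34 for dissociation genes.

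With no minimum count the medians were 0.90 for surfactant in the whole library and 0.66 for alternative activation in alveolar macrophage-like cells. With at least 50 counts they were 1.30 for type 2 genes in the whole library, 1.42 and 1.73 for T cell or ILC2-like cell cycle and effector, and -0.47, 1.04, 1.03 and 1.10 for alveolar macrophage-like chemokines, alternative activation, profibrotic and cell cycle genes. With each cell weighted the same, whole-library medians were 0.14 for surfactant, 1.00079 for transitional, 0.49 for type 2, 1.03 for alternative activation, -1.66 for interferon, -0.83 for MHC class I and 0.28 for matrix genes. That setting gave -0.46 for B cell-like and 0.47 for T cell or ILC2-like cell cycle, -0.13, 1.19 and -0.38 for alveolar macrophage-like chemokines, profibrotic and MHC class II, 1.38 and -0.22 for endothelial-like activation and dissociation, and 0.73 for secretory-like dissociation genes.

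Doublets kept brought the T cell or ILC2-like cell cycle median to 0.0724. Cluster 18 alone, which held 82 injured and 20 control cells, gave 1.19 for transitional, 1.79 for MHC class II, where the sign changed, 0.59 for MHC class I and 1.01 for dissociation genes. Only cells of at least 2000 UMIs gave -0.83 for MHC class II and 0.68 for MHC class I in alveolar epithelial-like cells. The effector median was 0.21 in cluster 8 alone and 0.37 in cluster 5 alone. The total without genes over 1% gave 1.01, -0.38 and 0.98 for alveolar macrophage-like alternative activation, MHC class II and cell cycle genes. Without members under 20% of their highest class level, which leaves out genes that free RNA or doublets could bring in, the medians were 0.39, 0.48 and 1.10 for alveolar macrophage-like alternative activation, profibrotic and cell cycle genes and 2.48 for T cell or ILC2-like effector genes, and of 18 medians 14 stayed. A member's level was taken in the library where it was higher, so this setting keeps members partly by their change, and a median further from 0 under it adds no support. In 11 other class lists fewer than 5 members were left, among them MHC class II, chemokine and dissociation genes in alveolar macrophage-like cells and MHC class II and dissociation genes in alveolar epithelial-like cells.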

Other observations

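The tests on mixing of alveolar macrophages by a technical shift, on interferon genes by class shares and depths and by free RNA in each class, and on Siglecf by free RNA and by both eosinophil explanations were chosen only after the result was seen. Outside the comparisons above, interferon response genes were also lower in 12 of 12 neutrophil-like (median log2 ratio -2.90, -3.31 to -2.69), 8 of 11 B cell-like (-0.86, -1.21 to -0.64) and 10 of 12 T cell or ILC2-like cases (-0.75, -0.99 to -0.56). MHC class I genes had medians of -0.70 in neutrophil-like, -0.29 in B cell-like, -0.08 in T cell or ILC2-like and 0.42 in secretory-like cells. UMIs of Tnfrsf9, a costimulatory receptor gene, were found in 9.77% of injured and 1.003% of control T cell or ILC2-like cells thinned to 1000 UMIs, in 19.5% and 1.33% without thinning (median depths 4895 and 5883 UMIs), and in 0 of 58 and 0 of 314 thinned B cell-like cells. The chemokine transcripts of Ccl17 lay mostly in cDC2-like cells (68.8% of injured counts), those of Ccl22 in mature dendritic cell-like cells (90.0%), and those of Alox15, a lipoxygenase gene, in cDC2-like cells (92.0%).

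The 4 injured cells with UMIs of at least 2 eosinophil markers had 512, 1294, 938 and 805 UMIs, and 3 of the 4 had no UMI of Csf3r, Cxcr2 or S100a8, genes of neutrophils. The cells with 512 and 805 UMIs had UMIs of Siglecf, Prg2 and Ear6, and the latter also had 2 UMIs of S100a9.

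Siglecf transcripts in injured neutrophil-like cells were weighed against free RNA, macrophage RNA and eosinophils. Free RNA would reach other cells alike, yet 15.8% (12.8–19.2) of neutrophil-like cells had a Siglecf UMI against 0.356% (0.0431–1.28) of pooled B, T, endothelial and C1q macrophage-like cells. Alveolar macrophage RNA in doublets or droplets would bring Marco, Spp1, Chil3, Ctsd and Ear2, whose excess was 0.126% (0.0318–0.239) of the level needed. Eosinophils inside the neutrophil clusters cannot be told apart, since Csf3r, Cxcr2 or S100a8 was found in 100% (95.8–100) of the 85 cells and in 99.6% of the others but S100a8 led both clusters and all 3 led cluster 0, and with Csf3r or Cxcr2 alone the shares were 83.5% (73.9–90.7) and 93.4%. Nor can they be told apart under 1000 UMIs, since 0 of 2 Siglecf cells (0%, up to 84.2%), both among the 4 cells above, had such a gene against 90.9% of the others, and expression of Siglecf by neutrophils themselves also stays open and was not tested.

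Alveolar macrophage-like cells of the 2 libraries shared no cluster apart from 1 cell, and had 1.86% of the expected neighbours from the other library. A technical shift in every cell type would part other classes as well, yet B cell-like cells had 40.1% and T cell or ILC2-like cells 53.5%, while neutrophil-like cells had 9.79%. With each class embedded alone the shares were 3.04% for alveolar macrophage-like, 28.3% for B cell-like, under the 30% that the test asked for, and 34.0% for T cell or ILC2-like cells. Without 11649 genes higher in other classes, as a test of free RNA, the share was 4.66%, and at 5000 UMIs per cell, as a test of depth, 3.38%. A state of these cells particular to the library titled injured may explain the split, but it cannot be told apart from differences between the animals or the processing days of the 2 libraries, since there was 1 library per group.

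Interferon response genes were lower in the injured library, at 528 against 2127 CPM for the summed list, a log2 change of -2.01. With each class at its control level (its injured level if it held under 10 control cells) and the class shares and depths of the injured library, the sum was 1374 CPM, or 31.3% of that change. Free RNA in the control library would hold these genes at a fixed ratio to Scgb1a1, yet the ratio in neutrophil-like cells was 20.9 times that in alveolar macrophage-like cells, and 10.1 times in endothelial-like cells. It was 1.57 times in T cell or ILC2-like cells, as free RNA would give, and 2.91 times in B cell-like cells. The 300 control T cell or ILC2-like cells held 2027 list and 6584 Scgb1a1 counts, against 1243 and 6347 in 402 alveolar macrophage-like cells. Scgb1a1 was thus not spread alike over the cells of both classes, and free RNA may account for part or all of the T cell or ILC2-like counts. In B cell-like cells it cannot be told apart. A difference in interferon signalling between the animals of the libraries, in either direction, stays open for these classes and was not tested.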
